A study of Mus musculus with 14 samples.

How the data were processed

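The starting point was the table of raw read counts deposited by the authors, with 54532 genes in rows and 14 libraries in columns, and the counts were used as they were. Per the submitters' processing notes, reads had been trimmed with fastp, aligned with STAR to mouse genome mm10 and counted with featureCounts; versions, the annotation release and the strandedness of the library preparation were not given. Total RNA had been prepared with a NEBNext Ultra RNA kit. Where strand is not known, reads of overlapping genes on opposite strands cannot be told apart.

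Columns were matched to the 14 samples by their names. Totals were 16169408 to 22089520 reads per library, and at least 99.88% of them lay in tested genes. Genes encoded by mitochondrial DNA held 1.016 to 1.486% of reads. Y chromosome genes had 0 reads and Xist had 455881, so that no library came from male cells in part or in whole. Of the symbols 27 had been turned into dates by a spreadsheet program, and 102 symbols stood in more than 1 row; such genes were handled by their Ensembl identifier.

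Genes were filtered with filterByExpr of edgeR by group, which left 14704 genes, 12336 of them protein-coding. TMM scaling and a quasi-likelihood negative binomial fit of edgeR used all 14 libraries with 1 coefficient per group, so that 10 residual degrees of freedom remained; the biological coefficient of variation of the dispersion trend at the median gene was 0.118. In total 6 contrasts were tested: 3 fixed as main ones (IL-33 against medium, ILC2sn against medium, IL-33-ILC2sn against ILC2sn), IL-33-ILC2sn against IL-33 and against medium, and the difference of the 2 effects of IL-33. P-values were adjusted by Benjamini-Hochberg within each contrast over all tested genes, with a threshold of 0.05. Where a group had 3 reads or fewer of a gene in all its libraries, the fold change was given as a ratio of reads per depth with a 95 percent interval of the counting error, or as at least so many fold against a floor of 3 reads. These intervals leave out the spread between replicates.

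Genes named by rule were the 8 with the largest significant rise and fall of each main contrast, and the 5 of each other contrast, among those with a mean of at least 5 CPM in the higher group and no overlap of libraries between the groups, without names of predicted genes or pseudogenes, and the members of the lists with the smallest p, up to 4 for a list that passed and 2 for another. Stem cell, receptor and lineage genes fixed beforehand were followed whatever their result. The cytokine genes Il9 and Csf2, below the CPM limit, were named as members of the cytokine list, and Klf2, Hspa5, Igkc, Il9 and Lipg were given more room after their values had been seen. Il33 and Il5ra did not pass the filter.

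Before the data were opened, 33 gene lists were written from general knowledge; 1 of them (genes that tell male from female cells) served only as a sample check, and 32 were tested with camera of limma on voom values with a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a contrast. At least 5 members had to be tested. Some lists are named in short below. The list of p53 targets also holds apoptosis genes, and that of immediate early genes also holds heat shock genes. Myc targets include ribosome biogenesis genes, and the interferon-gamma list includes antigen presentation genes. A shift of such a list does not isolate the part it is named after. For each list, members were counted that passed over all genes and when adjusted over the list alone. The 2 alternatives were camera with a correlation estimated from the data and fry. The sign of the median of the members, of their mean and of the test was the same for every list that passed. Mean log2 differences of a list are those of the log2 CPM of its members, and mean log2 fold changes those of the fit.

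Sample structure was read from the 500 most variable genes on log2 CPM with a prior count of 2. Trends with gene length and GC content were measured as Spearman rank correlations, with GC content known for 99.9% of tested genes. After these trends and the split of the ILC2sn group had been seen, 3 alternatives were added: fits without ILC2sn libraries 3 and 4, fits without libraries 1 and 2, and offsets that remove a smooth curve on length and GC content from each library. The alternatives fixed beforehand were other size factors, DESeq2 and limma-voom in place of edgeR, no filter, a stricter filter (5 CPM in 3 libraries), protein-coding genes only, only the groups of a comparison, a block on the replicate number, and leaving out each library in turn.

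Comparisons with a shared control were judged with 20 simulated data sets of negative binomial counts that kept each gene's overall mean and dispersion, and by giving each comparison 2 medium libraries of its own. Replicate libraries of a group differed by more than Poisson counting, with a chi-square per degree of freedom of at least 3.02.

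The whole procedure was tried on simulated data with 200 changed genes per contrast. It recovered 46.3, 55.2, 56.7, 44.8, 55.2 and 20.9% of genes changed 1.5-fold in the 6 contrasts in the order given above, 67.2, 79.1, 70.1, 85.1, 76.1 and 58.2% of those changed 2-fold, and 93.9, 97, 92.4, 90.9, 97 and 80.3% of those changed 4-fold. Of the genes called, 3.2, 3.4, 3.7, 6.3, 5.1 and 5.9% were unchanged ones. The changed list was recovered in each contrast, and 0 of 31 unchanged lists were called. The simulated genes were drawn independently of each other, so this does not judge the preset correlation on lists whose members move together. The simulated libraries also held neither the split of the ILC2sn group nor a trend on gene length or GC content. The shares of unchanged genes are therefore not the error rates of the gene calls in the data, least of all in contrasts with ILC2sn. In the data the estimated correlation of the ribosomal protein list was 0.915 in IL-33 against medium.

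Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.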

Results

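LSK cells are the lineage-negative, Sca1-positive, cKit-positive cells of bone marrow, the fraction that holds the haematopoietic stem cells and the multipotent progenitors. They were sorted from BL/6 wild-type mice and cultured for 24 h with stem cell factor (SCF) and Flt3 ligand (Flt3L) before RNA sequencing. The medium group (n = 4) received nothing more, and the IL-33 group (n = 3) received interleukin-33 (IL-33), a cytokine of the IL-1 family. The ILC2sn group (n = 4) received supernatant of group 2 innate lymphoid cells (ILC2s), lymphocytes without antigen receptors that are known for making IL-5 and IL-13. The IL-33-ILC2sn group (n = 3) received supernatant of ILC2s that had themselves been given IL-33. The ILC2s had been kept with IL-2 and IL-7, and no step that would remove IL-2, IL-7 or IL-33 from the supernatants was described. An effect of a supernatant could therefore come from these added cytokines as well as from ILC2 products.

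The deposited table held raw read counts of 54532 genes in 14 libraries of 16169408 to 22089520 counted reads, and 14704 genes had enough reads to be tested. Expression is given as CPM, the reads of a gene scaled to a common library depth, mean ± SD of the replicate libraries, and 1 read in the shallowest library equalled 0.0618 CPM. The largest rises and falls named for a comparison are those of genes with at least 5 CPM in 1 of the groups and without overlap between the libraries of the 2 groups. The first principal component of the 500 most variable genes held 35.2% of their variance. On it medium libraries lay at −15.18 to −12.2, IL-33 libraries at 1.7 to 2.65 and IL-33-ILC2sn libraries at 16.98 to 20.41. The ILC2sn libraries did not form 1 group, with libraries 1 and 2 at −7.79 and −6.44 and libraries 3 and 4 at 4.46 and 1.11. On the second component (16.8% of the variance) libraries 3 and 4 lay at 18.76 and 15.82, and libraries 1 and 2 at −5.31 and −9.93. The deviation of a library from the mean of all libraries followed gene length in opposite directions in the 2 pairs, with Spearman rank correlations of 0.56 and 0.668 in ILC2sn 1 and 2 and of −0.705 and −0.656 in ILC2sn 3 and 4. The labels do not say whether replicates were separate mice or separate cultures, so the p-values may measure technical spread only.

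**Figure D1:**
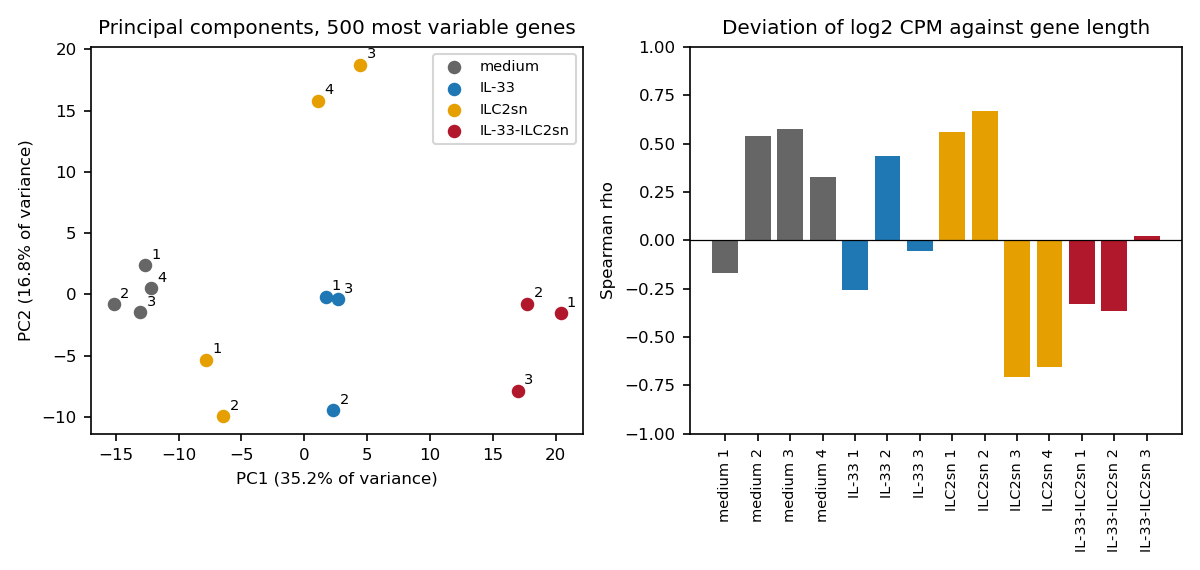
Left, the first 2 principal components of the 500 most variable genes, 1 point per library, coloured by group and numbered by replicate. Right, Spearman rank correlation of each library's deviation from the mean of all libraries with gene length, 1 bar per library.

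With IL-33 alone the LSK cultures expressed type 2 cytokine genes, of which almost no transcript was read in medium. The bulk values do not tell which cells of the sorted fraction expressed them. Il13 (ENSMUSG00000020383, chr11:53631324–53634702, minus strand, mm10) encodes IL-13 and stood at 0.0279 ± 0.0323 CPM in medium (n = 4) and 14.3 ± 3.1 CPM with IL-33 (n = 3). That was 2 reads against 794, a ratio of 510 (95 percent interval of the counting error 141 to 4220). Il5 (chr11:53720794–53725106, plus strand) went from 1 read to 247 reads and reached 4.51 ± 0.406 CPM, a ratio of 317 (interval 56.5 to 12600). Il9 (chr13:56479277–56482246, minus strand) had 0 reads in medium and 69 with IL-33, at least 29.6-fold against a floor of 3 reads. Csf2, the gene of the myeloid growth factor GM-CSF, rose from 0.0857 ± 0.0351 to 1.66 ± 0.52 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes, the adjusted p was 2.72e-08 for Il13, 9.73e-07 for Il5, 0.0138 for Il9 and 0.0165 for Csf2. The call of Il9 was lost without IL-33 library 2, and that of Csf2 in 6 of 17 alternative analyses.

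In all, IL-33 changed 24 genes against medium, 23 of them upward and 12 by at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p < 0.05). An unadjusted p below 0.05 was found for 924 genes. Beside the cytokines the largest rises with at least 5 CPM in 1 group were those of Lipg, Spint1 and Id1. Lipg (ENSMUSG00000053846, chr18:74939322–74961263, minus strand) encodes endothelial lipase and rose from 0.614 ± 0.169 to 7.08 ± 3.06 CPM (log2 fold change 3.53, SE 0.49, edgeR adjusted p = 0.00735). Spint1 (ENSMUSG00000027315, chr2:119237362–119249527, plus strand), the gene of a Kunitz-type inhibitor of serine proteases, rose from 1.51 ± 0.53 to 6.23 ± 0.313 CPM (2.04, SE 0.21, edgeR adjusted p = 0.000257). Id1 (ENSMUSG00000042745, chr2:152736251–152737410, plus strand) encodes an inhibitor of helix-loop-helix transcription factors and rose from 3.05 ± 0.44 to 11.5 ± 0.467 CPM (1.90, SE 0.15, edgeR adjusted p = 2.09e-05). Smaller rises by edgeR were those of the stanniocalcin gene Stc2 (0.89, adjusted p = 0.0363), the kinase gene Pim1 (0.85, adjusted p = 0.0243) and the amidase gene Naaa (0.79, adjusted p = 0.0268). Lgals3, which encodes galectin-3, rose from 11 ± 0.397 to 18.7 ± 0.273 CPM (0.76, edgeR adjusted p = 0.00267). The only fall was that of Acox3, a gene of peroxisomal fatty acid oxidation, from 44.1 ± 0.669 to 33 ± 0.0875 CPM (−0.42, edgeR adjusted p = 0.0482). Without IL-33 library 2 only 6 genes passed, without IL-33 library 1 there were 29, and without IL-33 library 3 or any 1 of the medium libraries 11 to 14. Il13, Il5, Spint1, Id1 and Lgals3 kept their calls in every alternative analysis in which they were tested. With ILC2sn libraries 3 and 4 left out of the fit 167 genes passed, and with libraries 1 and 2 left out 121, both choices made after seeing the data.

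Gene lists fixed before the data were opened placed these few genes in a wider, small shift. With limma's camera at a preset inter-gene correlation of 0.01, 20 of 32 lists moved with IL-33, 18 of them upward, and 8 kept their call with an estimated correlation. Upward among these 8 were cytokines and chemokines, targets of STAT5, ILC2 identity genes, glycolysis and the hypoxia response. So were the unfolded-protein and amino acid response and the immediate early and heat shock genes. Stromal and endothelial genes, which fell, were the last. Of 23 cytokine and chemokine genes 4 rose and 7 rose when adjusted over the list alone (camera adjusted p = 6.32e-14). Of the 19 targets of STAT5, a transcription factor downstream of many cytokine receptors, 3 rose (Pim1 0.85, Pim2 0.64 and Id1), and over the list alone 10 rose and 1 fell (camera adjusted p = 8.39e-11). ILC2 identity genes rose as a list (4 of 29, the same 4 cytokine genes, 7 over the list alone, camera adjusted p = 8.39e-11). Its 23 members that do not encode cytokines had a median log2 fold change of 0.151, and 0 of them passed by edgeR.

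Metabolic and stress genes moved little 1 by 1 but together. None of the 25 glycolysis genes passed over all genes and 16 rose over the list alone (camera adjusted p = 5.91e-15); the glucose transporter gene Slc2a1 went from 71.2 ± 4.34 to 97.2 ± 13 CPM (0.45, edgeR adjusted p = 0.079). Hypoxia genes rose likewise (28 tested, 1 up, 13 over the list alone, camera adjusted p = 9.32e-13). Genes of the unfolded-protein and amino acid response rose as well (45 tested, 1 up, 11 over the list alone, camera adjusted p = 8.22e-18), and so did immediate early genes (30 tested, none alone, camera adjusted p = 0.000109). Stromal and endothelial genes, 8 tested, fell as a list (2 down over the list alone, camera adjusted p = 0.000247).

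The remaining calls of camera in this comparison were lost with an estimated correlation. Upward were NF-kB targets (27 tested, 5 over the list alone, camera adjusted p = 1.24e-09, and 0.103 with an estimated correlation), Myc targets (59 tested, 7.64e-10 and 0.0689), cholesterol synthesis genes (25 tested, 4 over the list alone, 4.52e-10 and 0.0513). The neutrophil lineage rose by camera too (32 tested, Gfi1 up at 0.67, 10 up and 1 down over the list alone, 8.02e-10 and 0.0689). Also upward by camera were STAT3 targets (18 tested, 1 up, 5 over the list alone, 2.91e-05 and 0.0716), interferon-gamma response genes (33 tested, 1 over the list alone, 0.000469 and 0.408) and oxidative phosphorylation genes (57 tested, 0.00059 and 0.651). The same held by camera for STAT6 targets (17 tested, 5 up and 1 down over the list alone, 0.00158 and 0.0689), eosinophil lineage genes (17 tested, 1 up, 4 over the list alone, 0.00161 and 0.0689), p53 targets (36 tested, 0.0203 and 0.128) and ribosomal protein genes (61 tested, 0.0326 and 0.803). Megakaryocyte and erythroid genes fell by camera (38 tested, none alone, 0.0203 and 0.0716). Some rises were largest in IL-33 library 2, where NF-kB, STAT3 and interferon-gamma lists had mean log2 differences from medium of 0.644, 0.562 and 0.588. The same values were 0.15, 0.129 and −0.009 in IL-33 library 1, and 0.214, 0.109 and 0.345 in library 3. Myc target and eosinophil genes went the other way, with lower values in library 2 than in library 1. Lists that did not pass by camera were the IL-33 receptor chain (adjusted p = 0.972), cytokine receptors (0.296), type I interferon response genes (0.832), long-term stem cell genes (0.0702), lymphoid priming genes (0.0837) and monocyte and dendritic cell genes (0.0837). The same was true by camera for mast cell and basophil genes (0.136), T and NK cell genes (0.925) and B and plasma cell genes (0.213). Of the cell cycle lists, S phase genes (0.832), G2 and M phase genes (0.528) and quiescence genes (0.0988) did not pass by camera either. Changes in this comparison followed gene length (rank correlation −0.411), which bears on lists of short genes such as the ribosomal and oxidative phosphorylation lists.

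LSK cultures given supernatant of ILC2s that had seen no IL-33 had higher neutrophil and glycolysis lists than medium, with small changes in few genes. The bulk values do not tell a shift within cells from a changed mix of cells. No cytokine gene was called by itself; Il13 stood at 0.128 ± 0.0946 CPM (n = 4) against 0.0279 ± 0.0323 CPM in medium (n = 4), a difference that did not pass (edgeR adjusted p = 0.573). By edgeR's quasi-likelihood test 19 genes passed a Benjamini-Hochberg adjusted p of 0.05, all of them higher with ILC2sn, and 1276 genes had an unadjusted p below 0.05. DESeq2's Wald test gave 97 higher and 12 lower genes, and limma-voom gave 17 higher genes. The largest rise was again that of Spint1, to 5.96 ± 1.04 CPM (log2 fold change 1.98, SE 0.20, edgeR adjusted p = 0.000487), followed by Id1 at 7.47 ± 1.45 CPM (1.28, SE 0.15, edgeR adjusted p = 0.00161). Lgals3 reached 23.6 ± 3.1 CPM (1.10, SE 0.09, edgeR adjusted p = 5.61e-05). F10, the gene of coagulation factor X (chr8:13037308–13056676, plus strand), went from 5.56 ± 0.423 to 10.7 ± 0.874 CPM (0.95, SE 0.10, edgeR adjusted p = 0.000556). Gfi1, which encodes a transcriptional repressor required for neutrophil differentiation, went from 14.5 ± 0.703 to 22.8 ± 1.27 CPM (0.65, edgeR adjusted p = 0.00663). Neutrophil granule genes were among the rest, with Pglyrp1 at 0.86 (adjusted p = 0.0196) and the elastase gene Elane at 0.69 (adjusted p = 0.0331), from 251 ± 14.6 to 404 ± 71.8 CPM, by edgeR with adjustment over all genes. The lactate transporter gene Slc16a3 rose by 0.98 (edgeR adjusted p = 0.0311).

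Of 32 lists 19 passed by camera at the preset correlation, 17 of them upward, and 4 kept their call with an estimated correlation. These 4 were neutrophil lineage (32 tested, 2 up over all genes and 23 over the list alone, camera adjusted p = 3.89e-23), glycolysis (25 tested, 3 and 19, 9.2e-22), hypoxia response (28 tested, 2 and 13, 2.92e-15) and cholesterol synthesis (25 tested, 1 and 10, 3.46e-13). Among their members, by edgeR with adjustment over all genes, were the glucose transporter gene Slc2a1 (0.55, adjusted p = 0.0196), the enolase gene Eno1 (0.53, adjusted p = 0.0331), the oxygen sensor gene Egln3 (0.53, adjusted p = 0.0427) and the mevalonate pathway gene Mvd (0.63, adjusted p = 0.0331). The calls of these 4 lists and of the eosinophil list were kept with either pair of ILC2sn libraries left out. Other calls were lost with an estimated correlation; of the 2 adjusted p in brackets the second is the one with that correlation. Upward by camera were the eosinophil lineage (1 up, 4 over the list alone, 6.92e-05 and 0.0507), oxidative phosphorylation (6.85e-05 and 0.578), the unfolded-protein and amino acid response (2 over the list alone, 1.38e-07 and 0.234), STAT3 targets (2 over the list alone, 0.00306 and 0.321) and ribosomal protein genes (0.00439 and 0.662). Others lost in this way were type I interferon (0.00439 and 0.42), NF-kB (1 over the list alone, 0.00683 and 0.42), immediate early genes (2 over the list alone, 0.00842 and 0.16) and monocyte and dendritic cell genes (1 up, 5 up and 2 down over the list alone, 0.0108 and 0.377), again by camera. Mast cell and basophil genes (2 over the list alone, 0.0108 and 0.0515), cytokines (0.0138 and 0.42), Myc targets (0.0254 and 0.42) and interferon-gamma (0.0352 and 0.627) were the last upward ones by camera. G2 and M phase genes (0.0398 and 0.42) and lymphoid priming genes (0.0466 and 0.348) were lower by camera. The targets of STAT5, on which IL-2 and IL-7 act, did not pass by camera (adjusted p = 0.071, 1 up, Id1). Nor did STAT6 targets (0.218), the IL-33 receptor chain (0.505), cytokine receptors (0.0732), long-term stem cell (0.323), megakaryocyte and erythroid (0.226), or ILC2 identity genes (0.686) by camera. Nor did T and NK cell (0.549), B and plasma cell (0.328) or stromal genes (0.105) by camera. S phase (0.851), quiescence (0.686) and p53 target genes (0.224) did not pass by camera.

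The ILC2sn group's inner split limits this comparison. Changes against medium followed gene length (rank correlation −0.613) and GC content (0.365). Without ILC2sn libraries 3 and 4 there were 29 changed genes, which held 11 of the 19, and without libraries 1 and 2 there were 5928, with 3006 higher and 2922 lower, by edgeR. Those 2 runs were added after seeing the data. In the first of them the camera call of ribosomal protein genes reversed (adjusted p = 7.52e-31), and so did that of oxidative phosphorylation (1.48e-17). Of the 35 ways to divide these 8 libraries into 2 groups of 4, 3 gave at least 19 changed genes, the actual one included, so a random grouping was not excluded as the source of the count. Leaving out medium library 1 or 2 left 6 changed genes, ILC2sn library 4 left 7, medium library 3 or 4 left 11, and ILC2sn library 1 gave 35. Spint1, Lgals3, F10 and Gfi1 kept their calls in every alternative analysis in which they were tested.

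IL-33 and the ILC2 supernatant raised 6 genes in common, Ak4, Gfi1, Lgals3, Id1, F10 and Spint1, against 0.03 expected if the 2 sets of higher genes were independent. Both comparisons use the same medium libraries, which alone makes them resemble each other. In 20 simulations of negative binomial counts without group differences no gene rose in both, a value that leaves out all effects and so does not judge the overlap. The covariance of the 2 sets of log2 fold changes reached at most 0.0293 in them, against 0.0489 in the data. The simulated counts held no trend on gene length, whereas both comparisons did (rank correlations −0.411 for IL-33 and −0.613 for ILC2sn). The excess therefore does not tell a shared response from a shared trend. When each comparison was given 2 medium libraries of its own, the covariance was 0.0242 or 0.0319, depending on which libraries went to which comparison, and the genes higher in both fell from 6 to 1 (of 7 and 4, or 5 and 3, higher genes). The simulations kept the medium libraries shared, so their 0.0293 is not a bound for these 2 covariances.

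Supernatant of IL-33-treated ILC2s changed many more genes than IL-33 or ILC2sn did against medium, an order that turned for ILC2sn without its libraries 1 and 2 (5928 genes against medium, and 4228 for IL-33-ILC2sn against ILC2sn). Against ILC2sn (n = 4), IL-33-ILC2sn (n = 3) changed 1424 genes, 659 upward and 765 downward, 91 and 89 of them by at least 2-fold, with a median absolute log2 fold change of 0.44 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p < 0.05). Cytokine genes were expressed as with IL-33 alone, and single neutrophil granule and lipid genes were among the largest rises and single monocyte genes among the largest falls. Il13 stood at 13.2 ± 2.46 CPM against 0.128 ± 0.0946 CPM, 807 reads against 10 (log2 fold change 6.59, SE 0.32, edgeR adjusted p = 5.45e-08). Il5 had 283 reads against 2, a ratio of 179 (interval of the counting error 49 to 1480, edgeR adjusted p = 7.33e-07), and Il9 had 87 against 0, at least 36.6-fold (edgeR adjusted p = 0.000752). Lipg rose as well, from 2.5 ± 1.87 to 53.3 ± 8.11 CPM (4.40, SE 0.36, edgeR adjusted p = 9.87e-06).

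**Figure D2:**
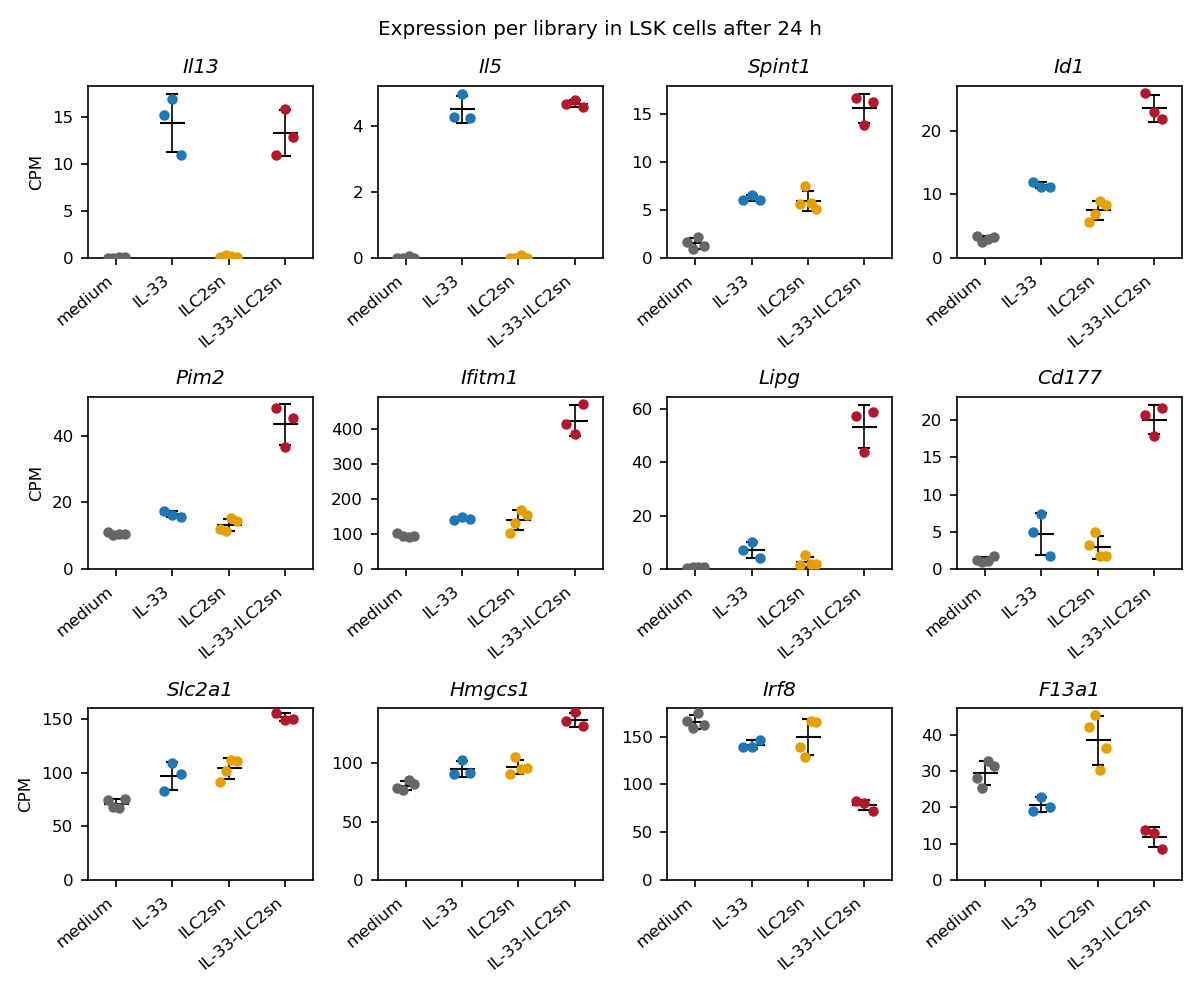
Expression in CPM of 12 genes, 1 point per library in each of the 4 groups; the bar gives the mean and its whisker the SD.

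The other large rises were those of Cd177, Lcn2, Ltf, Scd1, P4ha2 and Podxl. Cd177 encodes a neutrophil surface protein and went from 2.91 ± 1.53 to 20.1 ± 1.99 CPM (log2 fold change 2.78, SE 0.36, edgeR adjusted p = 0.000412). Lcn2 and Ltf, genes of the iron-binding granule proteins lipocalin 2 and lactoferrin, rose by 2.28 (adjusted p = 0.00029) and 2.23 (adjusted p = 0.00577) in edgeR's test with adjustment over all genes. The fatty acid desaturase gene Scd1 went from 16.3 ± 5.98 to 62.9 ± 4.18 CPM (1.95, edgeR adjusted p = 0.000239). The collagen hydroxylase gene P4ha2 went from 1.52 ± 0.503 to 5.74 ± 1.11 CPM (1.91, edgeR adjusted p = 0.000802) and the sialomucin gene Podxl from 2.73 ± 0.447 to 9.34 ± 2.1 CPM (1.77, edgeR adjusted p = 0.000206). The largest fall was that of F13a1, a monocyte and megakaryocyte gene of coagulation factor XIII (chr13:36867178–37050244), from 38.6 ± 6.77 to 11.8 ± 2.78 CPM (−1.72, SE 0.17, edgeR adjusted p = 5.15e-05). The histamine synthesis gene Hdc fell from 9.55 ± 0.935 to 3.51 ± 0.57 CPM (−1.45, edgeR adjusted p = 0.000948) and the fractalkine receptor gene Cx3cr1 from 9.68 ± 1.76 to 3.97 ± 1 CPM (−1.28, edgeR adjusted p = 0.000852). Ms4a6c (−1.25, adjusted p = 0.00365), the adhesion gene Vcam1 (−1.22, adjusted p = 0.00231), the fibronectin gene Fn1 (−1.18, adjusted p = 0.00663), the corepressor gene Tle2 (−1.18, adjusted p = 0.000593) and Bpifc (−1.16, adjusted p = 0.000266) completed the 8 strongest falls by edgeR with adjustment over all genes. Without 1 IL-33-ILC2sn library 731, 703 or 717 genes passed. Without ILC2sn libraries 3 and 4 there were 5285 (2983 higher, 2302 lower) and without libraries 1 and 2 there were 4228 (2410 higher, 1818 lower) by edgeR, runs added after seeing the data. Because of the split, 4 of 35 divisions of these 7 libraries gave at least 1424 changed genes, the actual one included, and a random grouping was not excluded either. The length trend was near 0 in this comparison (rank correlation −0.016), and that with GC content was −0.288. The value near 0 averages over opposite length trends in ILC2sn libraries 1 and 2 (0.56 and 0.668) and 3 and 4 (−0.705 and −0.656). It does not show that the comparison is free of a length trend.

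Targets of cytokine signalling rose beside the cytokine genes. Of 32 lists 23 passed by camera at the preset correlation, 17 upward and 6 downward, and 8 held with an estimated correlation. Of 19 STAT5 targets 12 rose, none fell and 7 were unchanged (14 up over the list alone, camera adjusted p = 1.48e-10), led by Pim2 (ENSMUSG00000031155, chrX:7878262–7883432, plus strand), a survival kinase gene, from 13.3 ± 1.82 to 43.5 ± 6.2 CPM (1.71, SE 0.11, edgeR adjusted p = 1.03e-06). Id1 rose by 1.66 (adjusted p = 9.92e-06), Pim1 by 1.02 (adjusted p = 0.000562), and the feedback inhibitor genes Socs3 by 1.55 (adjusted p = 0.00029) and Cish by 0.97 (adjusted p = 0.00199), by edgeR with adjustment over all genes. STAT3 targets rose (8 of 18, 11 over the list alone, camera adjusted p = 2.07e-08), as did STAT6 targets (8 up, 1 down of 17, 10 and 1 over the list alone, camera adjusted p = 1.3e-05). Among the latter was Chil3, a gene of alternative activation that is also in the neutrophil list (1.56, edgeR adjusted p = 0.000322). The STAT5, STAT3 and STAT6 lists share members such as Socs3 and Il4ra, so their rises are not independent of each other. These 3 lists held with an estimated correlation and with either pair of ILC2sn libraries left out. ILC2 identity genes rose too (8 up and 1 down of 29, 9 and 2 over the list alone, camera adjusted p = 0.00103), a call lost without ILC2sn libraries 3 and 4 (camera adjusted p = 0.0525), although the mean log2 difference of its members did not shrink (0.755, and 0.721 with all 4 libraries). Cytokines and chemokines (5 up and 1 down of 23, 7 and 1 over the list alone) passed camera (adjusted p = 0.00175) but not with an estimated correlation (0.249). Ccl6 of this list rose by 1.64 (edgeR adjusted p = 0.000617). Il12a, which is in the lymphoid priming list and not in this one, fell by 0.56. NF-kB targets (4 of 27 up, 4 over the list alone) gave a camera adjusted p of 0.0104, and 0.441 with an estimated correlation, with Bcl3 at 1.55 (edgeR adjusted p = 0.00666) and Gadd45b at 0.97.

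Receptor genes moved in both directions. Of 38 cytokine receptor genes 6 rose and 6 fell (9 and 11 over the list alone, camera adjusted p = 0.941). The IL-1 receptor gene Il1r1 went from 69.6 ± 4.6 to 106 ± 2.57 CPM (log2 fold change 0.61, edgeR adjusted p = 8.91e-05) and the shared beta chain gene Csf2rb of the IL-3, IL-5 and GM-CSF receptors from 88.1 ± 17.5 to 141 ± 13.5 CPM (0.68, edgeR adjusted p = 0.00509). The decoy receptor gene Il1r2 rose by 1.61 (edgeR adjusted p = 0.000345), and the M-CSF receptor gene Csf1r fell from 19.6 ± 2.18 to 9.1 ± 1.52 CPM (−1.11, edgeR adjusted p = 0.00021). The IL-33 receptor chain did not pass (1 up of 17, the adapter gene Tirap, 5 up and 2 down over the list alone, camera adjusted p = 0.239), and Il1rl1, the gene of the IL-33 receptor, was not called in any comparison.

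At the preset correlation granulocyte lists rose, and monocyte, dendritic and megakaryocyte or erythroid lists fell. The neutrophil list rose by camera (11 up and 2 down of 32, 14 and 3 over the list alone, adjusted p = 4.14e-05, and 0.201 with an estimated correlation), a call lost without ILC2sn libraries 1 and 2 (camera adjusted p = 0.157), although the mean log2 fold change went only from 0.494 to 0.447. Within it the granulocyte transcription factor gene Cebpe went from 10.2 ± 1.31 to 20.7 ± 2.79 CPM (1.02, edgeR adjusted p = 0.00029), while the myeloperoxidase gene Mpo fell by 0.36 (edgeR adjusted p = 0.0178). Eosinophil genes rose (7 of 17, 9 up and 3 down over the list alone, camera adjusted p = 0.00103, and 0.0633 with an estimated correlation), a call lost without ILC2sn libraries 1 and 2 (camera adjusted p = 0.0919), although the mean log2 difference hardly moved (0.262, and 0.276 with all 4 libraries). The monocyte and dendritic cell list fell (15 down and 4 up of 37, 18 and 6 over the list alone, camera adjusted p = 0.00024, and 0.109 with an estimated correlation), a call lost without ILC2sn libraries 3 and 4 (camera adjusted p = 0.0782, mean log2 fold change −0.159 in place of −0.323). Irf8, the transcription factor gene of monocytes and dendritic cells (chr8:120736358–120756694, plus strand), fell from 150 ± 18.6 to 78.5 ± 5.67 CPM (−0.93, SE 0.09, edgeR adjusted p = 3.98e-05) and Itgax, the gene of CD11c, from 15.5 ± 0.673 to 7.02 ± 0.991 CPM (−1.14, edgeR adjusted p = 1.31e-05). Megakaryocyte and erythroid genes fell (13 down and 3 up of 38, 16 and 3 over the list alone, camera adjusted p = 1.17e-05) and held with an estimated correlation (0.032) and with either pair of ILC2sn libraries left out. Among them were the repressor gene Gfi1b, from 106 ± 17.4 to 60.6 ± 7.93 CPM (−0.81, edgeR adjusted p = 0.00107), the platelet glycoprotein gene Gp5 (−0.73, edgeR adjusted p = 0.000536), Aqp1 (−0.67) and Mfsd2b (−0.63).

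Mast cell and basophil genes split evenly (6 up, 6 down of 28, 9 and 7 over the list alone, camera adjusted p = 0.297). Long-term stem cell genes fell by camera (6 down and 2 up of 40, 8 and 4 over the list alone, adjusted p = 0.0441, and 0.109 with an estimated correlation). Lymphoid priming genes did not pass (6 down and 2 up of 27, 6 and 3 over the list alone, camera adjusted p = 0.0663). Of other cell types, T and NK cell genes (1 up of 15, the granzyme gene Gzmb, camera adjusted p = 0.164) and B and plasma cell genes (2 down of 9, Cd72 and Ighm, 2 up and 4 down over the list alone, camera adjusted p = 0.175) did not pass. Stromal and endothelial genes fell (2 down of 8, Tie1 −0.46 and Col1a2 −0.66, 4 over the list alone, camera adjusted p = 0.0189, and 0.15 with an estimated correlation).

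Interferon genes went down as lists, although the interferon-induced membrane gene Ifitm1 rose from 139 ± 29 to 423 ± 43.7 CPM (log2 fold change 1.61, SE 0.13, edgeR adjusted p = 8.63e-06) and Ifitm3 by 0.87 (edgeR adjusted p = 0.00241). Reads of such close paralogs can be assigned to the wrong copy. Type I interferon genes (3 down and 1 up of 31, 5 and 1 over the list alone) had a camera adjusted p of 0.000386, and 0.314 with an estimated correlation. Interferon-gamma genes (7 down and 1 up of 33, 8 and 1 over the list alone) had a camera adjusted p of 0.006, and 0.491 with an estimated correlation, with Tap2 (−0.56, edgeR adjusted p = 0.000491), Gbp8 (−0.89) and Gbp9 (−0.71) among the falls. Both calls were lost without ILC2sn libraries 3 and 4, at camera adjusted p of 0.667 and 0.704, so they rested on the 2 libraries that stood apart.

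Metabolic lists rose together. Cholesterol synthesis was the most complete, with 15 of 25 genes up, none down and 19 up over the list alone (camera adjusted p = 3.85e-13, and 0.0351 with an estimated correlation). Hmgcs1 went from 96.7 ± 5.79 to 137 ± 5.81 CPM (0.51, edgeR adjusted p = 0.000483), and Cyp51, Idi1 and Mvd rose by 0.56, 0.57 and 0.66. Glycolysis genes rose (15 of 25, 17 up and 1 down over the list alone, camera adjusted p = 1.11e-09, and 0.0467 with an estimated correlation), among them Slc2a1 from 104 ± 9.42 to 152 ± 3.63 CPM (0.54, edgeR adjusted p = 0.00199) and Pgam1 (0.56, edgeR adjusted p = 0.000398). Hypoxia genes rose (11 of 28, 12 up and 1 down over the list alone, camera adjusted p = 5.41e-08, and 0.0859 with an estimated correlation), with Stc2 at 1.17, Ero1l at 0.94 and Anxa2 at 0.72. The unfolded-protein and amino acid list rose (17 of 45, 21 over the list alone, camera adjusted p = 5.74e-12, and 0.0631 with an estimated correlation), with the chaperone gene Hspa5 from 715 ± 44.7 to 1010 ± 32.7 CPM (0.49, edgeR adjusted p = 0.00029). Myc targets rose (12 of 59, 20 over the list alone, camera adjusted p = 3.5e-10, and 0.0631 with an estimated correlation). Immediate early and heat shock genes rose (8 up and 1 down of 30, 14 and 2 over the list alone, camera adjusted p = 2.27e-05, and 0.0351 with an estimated correlation), led by Atf3 at 2.12 (edgeR adjusted p = 0.000852). All of these calls were kept with either pair of ILC2sn libraries left out.

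The list of p53 target and apoptosis genes rose (5 up and 1 down of 36, 5 and 1 over the list alone, camera adjusted p = 0.00264, and 0.0768 with an estimated correlation). In it the death gene Pmaip1 went from 10.1 ± 1.4 to 24.5 ± 1.7 CPM (log2 fold change 1.28, edgeR adjusted p = 5.15e-05). Of the cell cycle lists, S phase genes rose (4 up and 1 down of 50, 5 and 1 over the list alone, camera adjusted p = 0.0141, and 0.249 with an estimated correlation), with Ccne1 at 0.66 and Rrm2 at 0.38 (edgeR adjusted p = 0.0019). G2 and M phase genes (1 up and 1 down of 62, camera adjusted p = 0.663) and quiescence genes (2 up and 1 down of 25, camera adjusted p = 0.951) did not pass; Klf2 in the latter rose by 1.23 and Pdcd4 fell by 0.68. Oxidative phosphorylation genes passed (1 up of 57, camera adjusted p = 0.013, and 0.737 with an estimated correlation), but the direction reversed without ILC2sn libraries 1 and 2 (camera adjusted p = 4.29e-07). Without the same libraries the calls of p53 targets (camera adjusted p = 0.201), S phase genes (0.285), cytokines (0.38) and NF-kB targets (0.262) were lost too. Their mean log2 differences kept their sign and went from 0.191 to 0.111, from 0.084 to 0.035, from 0.962 to 0.698 and from 0.26 to 0.146. The calls of 2 lists were lost without either pair, those of long-term stem cell genes (camera adjusted p = 0.26 without libraries 1 and 2, and 0.0962 without 3 and 4) and of stromal genes (0.0532 and 0.114). Their mean log2 differences were −0.052 and −0.051 for the former and −0.309 and −0.213 for the latter. Ribosomal protein genes did not pass (61 tested, camera adjusted p = 0.364). Their mean log2 difference was 0.549 without libraries 3 and 4 and −0.394 without libraries 1 and 2, so opposite differences cancelled.

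**Figure D3:**
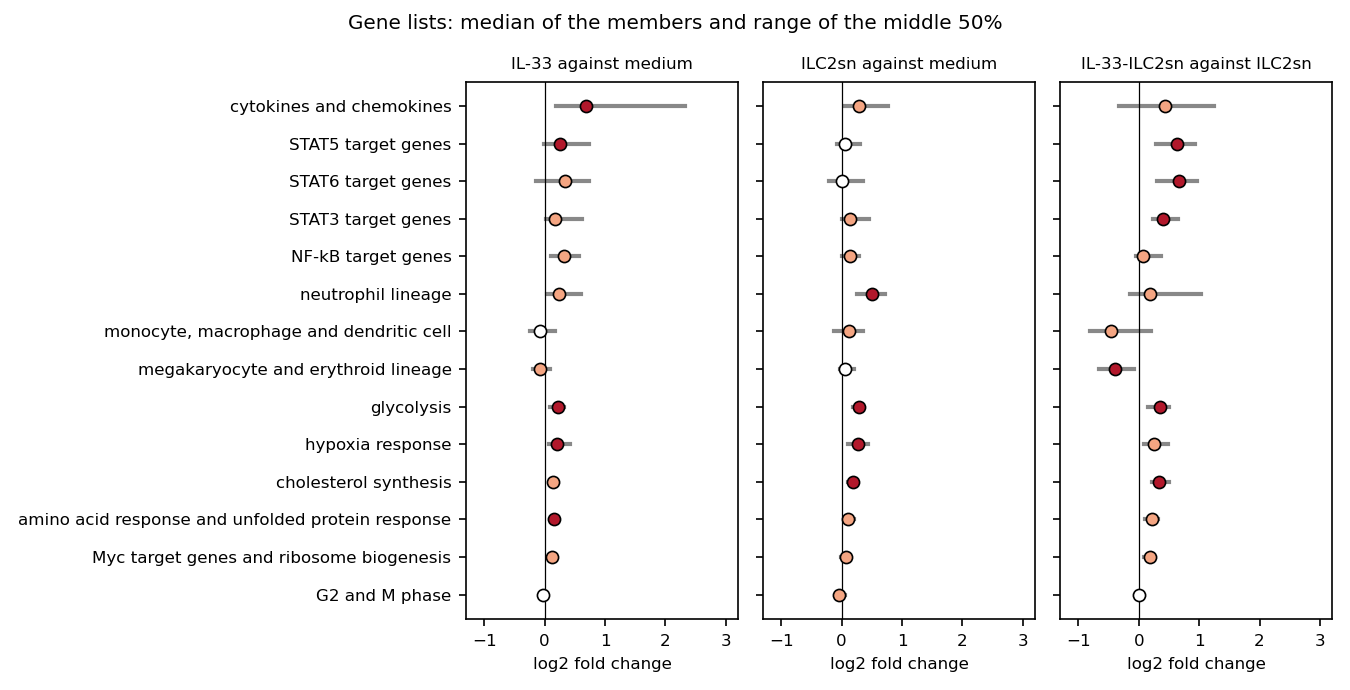
Median log2 fold change of the tested members of 14 gene lists in 3 comparisons, with a line over the middle 50% of members. Dark red points passed by camera with the preset and with an estimated correlation, light red with the preset one only, and white ones did not pass.

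IL-33-ILC2sn was also set against IL-33 alone. Whether the LSK cells of the former were exposed to IL-33 was not measured. For the type 2 cytokine genes no difference was called, with Il13 at 13.2 ± 2.46 against 14.3 ± 3.1 CPM (n = 3 each), whereas the neutrophil, cholesterol synthesis and glycolysis lists were higher. In all, 569 genes changed, 286 up and 283 down, 106 of them by at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p < 0.05). Lipg led with 53.3 ± 8.11 against 7.08 ± 3.06 CPM (log2 fold change 2.91, SE 0.36, edgeR adjusted p = 0.000678). Cd177 (2.10, adjusted p = 0.0066), Scd1 (2.02, adjusted p = 0.00076), P4ha2 (2.01, adjusted p = 0.0025) and the cathelicidin gene Camp (1.85, adjusted p = 0.0018) followed by edgeR. Camp stood at 15 ± 2.17 against 4.14 ± 2.27 CPM. The strongest falls by edgeR were those of the matrix gene Chad, from 5.41 ± 0.687 to 2.04 ± 0.355 CPM (−1.40, adjusted p = 0.00247), Cx3cr1 (−1.28, adjusted p = 0.0025), Gbp8 (−1.11, adjusted p = 0.00572), Cxcr5 (−1.07, adjusted p = 0.00571) and Abcg3 (−1.07, adjusted p = 0.0109). The call of Abcg3 was lost without IL-33 library 3 and without IL-33-ILC2sn library 3. Pim2 (1.40, adjusted p = 3.94e-05), Ifitm1 (1.56, adjusted p = 5.06e-05), Klf2 (1.66, adjusted p = 0.000877), Cebpe (1.15, adjusted p = 0.000651) and Irf8 (−0.85, adjusted p = 0.000424) changed as in the previous comparison, by edgeR with adjustment over all genes.

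Of 32 lists 17 passed by camera, 14 up and 3 down, and 8 held with an estimated correlation. The 8 were cholesterol synthesis (11 of 25 up, 21 over the list alone, camera adjusted p = 1.3e-20), glycolysis (13 of 25, 20 over the list alone, 3.54e-18), neutrophil lineage (12 of 32, 19 over the list alone, 2.19e-15), hypoxia (8 of 28, 18 over the list alone, 4.74e-12) and STAT3 targets (6 of 18, 10 over the list alone, 4.98e-10). The others, again by camera, were eosinophil lineage (6 of 17, 7 over the list alone, 2.86e-06), immediate early genes (3 of 30, 5 over the list alone, 1.28e-05) and STAT6 targets (3 up and 1 down of 17, 0.00011). Calls of camera lost with an estimated correlation, whose adjusted p stands second in the brackets, were, upward, the unfolded-protein and amino acid response (5 of 45, 4.98e-10 and 0.0964), Myc targets (2 of 59, 5.77e-07 and 0.12) and STAT5 targets (4 of 19, 6 over the list alone, 2.55e-06 and 0.0689). So were, by camera, oxidative phosphorylation (none of 57, 0.000582 and 0.699), p53 targets (2 of 36, 0.00597 and 0.102) and S phase (3 of 50, 0.00852 and 0.214). Downward and lost likewise by camera were interferon-gamma (5 of 33, 7 over the list alone, 0.000159 and 0.432), megakaryocyte and erythroid (4 of 38, 10 down and 3 up over the list alone, 0.0057 and 0.0522) and lymphoid priming genes (2 down and 1 up of 27, 0.0197 and 0.155). Cytokines did not pass (2 of 23 up, Ccl6 and Ccl4, camera adjusted p = 0.937), and monocyte and dendritic cell genes did not either (9 down and 4 up of 37, camera adjusted p = 0.152). The remaining 13 lists did not pass by camera. Leaving out single libraries lowered the count of genes to 315, 365 and 242 (IL-33 libraries 1 to 3) and 257, 292 and 296 (IL-33-ILC2sn libraries 1 to 3). The ILC2sn libraries are not compared here but enter the filter, the scaling and the dispersion. There were 1789 changed genes without libraries 3 and 4, and 1530 without libraries 1 and 2, choices made after seeing the data.

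Against medium (n = 4), IL-33-ILC2sn (n = 3) changed 2430 genes, 1205 up and 1225 down, 231 and 202 of them by at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p < 0.05). After 24 h the cultures expressed type 2 cytokine genes and had raised neutrophil, glycolytic and sterol genes. Il13 had 807 reads against 2, a ratio of 472 (interval of the counting error 130 to 3910, edgeR adjusted p = 3.56e-08). Il5 had 283 against 1 (ratio 331, interval 59 to 13100), and Il9 had 87 against 0, at least 33.9-fold. Lipg went from 0.614 ± 0.169 to 53.3 ± 8.11 CPM (log2 fold change 6.44, SE 0.43, edgeR adjusted p = 4.41e-07), Cd177 from 1.24 ± 0.349 to 20.1 ± 1.99 CPM (4.01, SE 0.41, edgeR adjusted p = 2.01e-05), and P4ha2 rose by 3.44 (edgeR adjusted p = 9.64e-06). Spint1 went from 1.51 ± 0.53 to 15.7 ± 1.52 CPM (3.37, SE 0.19, edgeR adjusted p = 1.04e-07). The strongest falls by edgeR were those of the small nuclear RNA gene Rn7sk (−1.90, adjusted p = 0.0137), the protease gene Htra3 (−1.77, adjusted p = 0.000149), Cx3cr1 (−1.65, adjusted p = 4.47e-05), Itgax (−1.47, adjusted p = 3.54e-07) and Chad (−1.39, adjusted p = 0.000367). The call of Rn7sk was lost without IL-33-ILC2sn library 1 and without library 3.

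Of 32 lists 22 passed by camera, 18 up and 4 down, with 13 holding with an estimated correlation. Upward and holding were cholesterol synthesis (21 of 25 up, 24 over the list alone, camera adjusted p = 4.79e-19), glycolysis (21 of 25, 3.63e-18), the unfolded-protein and amino acid response (27 of 45, 34 over the list alone, 1.09e-16), hypoxia (21 of 28, 2.01e-14), neutrophil lineage (22 up and 1 down of 32, 4.11e-14) and Myc targets (20 of 59, 33 over the list alone, 2.18e-11). Also holding by camera were STAT3 (12 up and 1 down of 18, 3.14e-09), STAT5 (11 of 19, 9.31e-09) and STAT6 targets (10 up and 1 down of 17, 7.96e-06), immediate early genes (14 up and 1 down of 30, 1.21e-06), eosinophil lineage (7 up and 1 down of 17, 2.31e-05) and ILC2 identity genes (8 up and 2 down of 29, 0.00244). Megakaryocyte and erythroid genes fell and held (12 down and 3 up of 38, 14 and 4 over the list alone, camera adjusted p = 0.0028). Lost with an estimated correlation, whose adjusted p again stands second, were, by camera, oxidative phosphorylation (4 of 57 up, 5.33e-06 and 0.547), cytokines (9 of 23, 7.43e-05 and 0.149), NF-kB targets (10 of 27, 0.000493 and 0.321), p53 targets (8 up and 2 down of 36, 0.00165 and 0.0523), ribosomal protein genes (none of 61, 0.00913 and 0.691) and S phase (5 up and 1 down of 50, 0.0268 and 0.279). Downward and lost likewise by camera were stromal (2 of 8, 0.00536 and 0.0777), lymphoid priming (6 down and 2 up of 27, 12 and 3 over the list alone, 0.0121 and 0.11) and long-term stem cell genes (11 down and 4 up of 40, 0.0219 and 0.064). Lists that did not pass by camera included monocyte and dendritic cell genes (15 down and 5 up of 37, adjusted p = 0.117), type I interferon (0.176), interferon-gamma (8 down and 2 up of 33, 0.411), cytokine receptors (9 up and 8 down of 38, 0.466) and mast cell and basophil genes (10 up and 5 down of 28, 0.0941). The 5 others did not pass by camera either. Changes followed gene length (rank correlation −0.384). Without IL-33-ILC2sn library 1 or 2 the count was 1382 or 1439, and with the ILC2sn libraries 3 and 4, or 1 and 2, taken out of the fit it was 5150 or 4849.

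The effect of IL-33 given to the cells and that of IL-33 given to the ILC2s shared a direction. Across all tested genes the log2 fold changes of IL-33 against medium and of IL-33-ILC2sn against ILC2sn had a Pearson correlation of 0.466 and a covariance of 0.0597; the 2 comparisons share no library. Without ILC2sn libraries 1 and 2, a run added after seeing the data, the correlation was 0.254. Of the 23 genes that rose with IL-33, 22 also rose in the second comparison, where 1.03 were expected, and the 1 gene that fell, Acox3, fell in both. In the other direction 1286 of the 1424 genes changed in the second comparison (90.3%) had the same sign with IL-33 alone. With IL-33 alone the median log2 fold change of the 1424, taken in the direction of the second comparison, was only 0.132. Their median absolute log2 fold change in the second comparison was 0.441. The share of equal signs over all tested genes was not counted. Genes are not independent of each other, so these shares describe the data and are not a test.

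**Figure D4:**
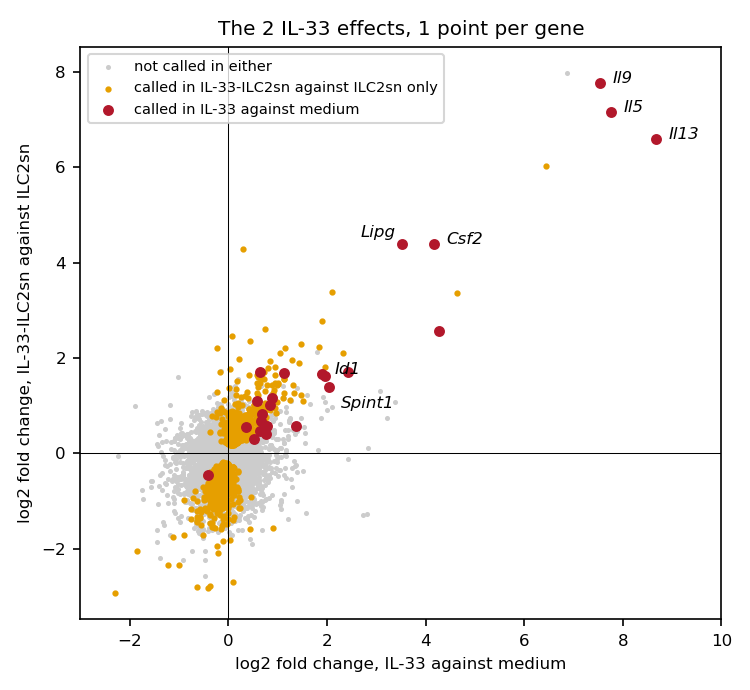
Log2 fold change of IL-33 against medium (horizontal) and of IL-33-ILC2sn against ILC2sn (vertical), 1 point per tested gene, with genes changed in either comparison coloured.

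The difference of these 2 effects, IL-33-ILC2sn against ILC2sn minus IL-33 against medium, passed for 5 genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p < 0.05), with 1174 genes at an unadjusted p below 0.05. Pim2 (log2 difference 1.06, SE 0.16, edgeR adjusted p = 0.0346), the zinc transporter gene Slc30a4 (0.77, SE 0.10, edgeR adjusted p = 0.017) and Il1r1 (0.59, SE 0.09, edgeR adjusted p = 0.0346) had the larger log2 fold change in IL-33-ILC2sn against ILC2sn. Slc35d3, a sugar transporter gene of platelet dense granules, fell more (−0.81, SE 0.09, edgeR adjusted p = 0.00389), from 80.3 ± 4.86 to 40.4 ± 2.08 CPM against 94.1 ± 1.74 to 82.9 ± 3.55 CPM, and Drc7, a gene of the cilium, did too (−0.73, SE 0.11, edgeR adjusted p = 0.0315). Of 24 alternative analyses Pim2 and Il1r1 lost their call in 13, Drc7 in 14 and Slc30a4 in 9. With the replicate number as a block no gene passed, so Slc35d3 lost its call there too. Slc30a4 went from 20.5 ± 1.24 to 35.1 ± 1.42 CPM and stayed at 23 ± 1.25 and 23 ± 0.615 CPM in medium and with IL-33. By camera 13 lists differed, and none held with an estimated correlation. This difference followed gene length (rank correlation 0.268) and GC content (−0.351). Without ILC2sn libraries 3 and 4 there were 372 changed genes, and without libraries 1 and 2 there were 2330, by edgeR in runs added after seeing the data. Without 1 library the count lay between 1 (medium library 2, for example) and 8 (ILC2sn library 3).

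Genes that define the LSK fraction were followed whatever their result, by edgeR with adjustment over all genes. Kit, the gene of cKit, stood at 475 ± 40.5 CPM in medium and 321 ± 10.4 CPM with IL-33-ILC2sn (log2 fold change −0.56), and fell by 0.41 against ILC2sn (edgeR adjusted p = 0.023). Ly6a, the gene of Sca1, rose by 1.67 against medium and by 0.95 against ILC2sn (edgeR adjusted p = 0.0355). Flt3 fell by 0.39 and 0.25 in these 2 comparisons, and the stem cell regulator gene Gata2 fell by 0.28 and 0.32. The stem cell marker gene Procr rose by 1.05 against medium (edgeR adjusted p = 0.0054). Il2ra rose by 0.81 and 0.90, and Il4ra by 0.30 against ILC2sn (edgeR adjusted p = 0.0186). Cd34, Il7r, Il2rb, Mki67, Mecom, Gata1, Epx, Prg2, Cpa3 and Dntt were not called in any comparison. The log2 fold change of Mki67 in IL-33-ILC2sn against ILC2sn was −0.07, but −0.43 without ILC2sn libraries 3 and 4 and 0.46 without libraries 1 and 2. Il33 and Il5ra had too few reads to be tested.

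Marker genes of other cells were read at low to moderate levels in every group. T and NK cell genes such as Nkg7 (37 CPM in medium, 40.7 CPM with IL-33-ILC2sn) and Lat (24 and 26.2 CPM), the B cell gene Cd79b (14.1 and 14.3 CPM) and the endothelial gene Pecam1 (144 and 127 CPM) are also transcribed in progenitors, so these levels do not tell a few other cells from the LSK cells themselves. Immunoglobulin genes were not changed by IL-33 alone; Igkc had 40 reads with IL-33, all in 1 library, and 0 in medium (edgeR adjusted p = 0.694).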

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

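The tests of explanations in the first 3 paragraphs were chosen after seeing the result they bear on; the regroupings of libraries and the difference of the 2 IL-33 effects with its list tests were planned.

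ILC2sn libraries 3 and 4 lay apart from libraries 1 and 2, with deviations that followed gene length in opposite directions. A trend on gene length and GC content was excluded as the whole cause, because the SD across genes of the difference between the pairs was 0.308 after the trend had been removed (0.434 before), and at most 0.143 for other halvings. A mislabelled culture of the IL-33 or IL-33-ILC2sn group was excluded, because Il13 was at most 0.147 CPM in these libraries and at least 10.9 CPM in the 6 libraries of the IL-33 and IL-33-ILC2sn groups. A different batch of supernatant, mice or library preparation could also part the pairs; the labels record none of these, and it was not tested.

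LSK cultures given IL-33 expressed Il13, Il5, Il9 and Csf2. Carry-over of ILC2 RNA or cells with a supernatant is excluded by the design for the 14.3 CPM of Il13 in the IL-33 group, which had no supernatant; for the IL-33-ILC2sn group it was not tested. A few ILC2s sorted with the LSK cells might multiply under IL-33. The median log2 fold change of the 23 ILC2 genes without cytokines was 0.151 (quartiles −0.007 to 0.361), which cannot tell. Whether the sort removed all ILC2s was not measured. Mast cell or basophil progenitors could be the source as well, and the median of 23 such genes, −0.065 (quartiles −0.217 to 0.244), cannot tell either.

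Neutrophil and metabolic lists were higher and monocyte and megakaryocyte or erythroid lists lower in IL-33-ILC2sn than in ILC2sn. After length and GC offsets all 5 lists kept direction and call by camera at the preset correlation (largest adjusted p 0.000156). At that correlation the trend was not the whole cause of these calls. With an estimated correlation, which was not run with offsets, the neutrophil and monocyte lists did not pass even without offsets (camera adjusted p = 0.201 and 0.109). Against either pair of ILC2sn libraries, glycolysis, cholesterol synthesis and megakaryocyte or erythroid genes kept their calls, again at the preset correlation (largest camera adjusted p 0.00648). Their mean log2 fold changes were 0.376, 0.385 and −0.239 without libraries 3 and 4, and 0.263, 0.345 and −0.241 without libraries 1 and 2. For these lists the values argue against the split of the ILC2sn group as the whole cause. For the neutrophil and monocyte lists, whose calls were each lost against 1 pair (largest 0.157), it was left open: the direction stayed, and the mean log2 fold change went from 0.494 to 0.447 for the former and from −0.323 to −0.159 for the latter. A lower share of LSK cells that raises every other cell type alike was left open. The megakaryocyte and erythroid list, whose call was kept against either pair, fell (mean log2 fold change −0.282, and −0.323 for the monocyte list). That fall cannot decide, because the 2 lists share genes such as Gfi1b and Flt3 with the stem cell and lymphoid priming lists.

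When the libraries were regrouped for IL-33 against medium, 1 of 35 divisions was as large, the actual one with 24 genes (the highest other 0). The same held for IL-33-ILC2sn against medium (1 of 35, 2430 genes, the highest other 0). Taken alone, each share speaks against a random grouping as the source of the gene count. It is the smallest that 35 divisions can give and was not adjusted for the number of comparisons regrouped. A random grouping was therefore not excluded. Nor can regrouping tell an effect of treatment from a difference of culture or batch between the groups, because the labels do not record these. For the difference of the 2 IL-33 effects a random grouping was left open. There 4 of 100 divisions were as large, the actual one included, but only a sample of the divisions was drawn and this share lies near 0.05. The highest other division gave 922 genes against 5, which points to a structure among the libraries. Regrouping did not exclude a random grouping for ILC2sn against medium (3 of 35, 19 genes, the highest other 4365). Nor did it for IL-33-ILC2sn against ILC2sn (4 of 35, 1424 genes, the highest other 3332). In these 2 comparisons the larger counts came from divisions that part ILC2sn libraries 1 and 2 from 3 and 4. For IL-33-ILC2sn against IL-33 (1 of 10, 569 genes, the highest other 0) there were too few divisions for a share below 0.05.

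Dixon's test was run on 142 sets of 4 replicates, each of a named gene or of a library measure such as depth. In 12 sets, all of genes, 1 library stood apart, with 7.1 expected by chance. In the ILC2sn group these were Lipg (5.28 CPM in library 2, others 1.3 to 1.75), Scd1 (25.2 in library 2, others 12.1 to 14), Bpifc (12.2 in library 2, others 16.2 to 17) and Camp (4.82 in library 1, others 6.53 to 6.81). In medium they were Abcg3 (10.5 in library 3), Drc7 (22.8 in library 3), Mpo (926 in library 3), Ly6a (15.4 in library 2), Cebpa (128 in library 2), and Il1rl1 (3.28), Epx (1.09) and Prg2 (3.99) in library 4. Epx and Prg2, genes of eosinophil granules, had 0 to 0.0571 CPM in the other 3 medium libraries.

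In all, 5 genes differed between the 2 effects of IL-33: Pim2 (log2 difference 1.064), Slc30a4 (0.773), Il1r1 (0.591), Drc7 (−0.733) and Slc35d3 (−0.808). By camera 13 lists differed: interferon-gamma (adjusted p = 8.47e-09), cholesterol synthesis (1.87e-06), monocyte and dendritic cell (4.2e-05), megakaryocyte and erythroid (0.000202), STAT3 (0.000278), type I interferon (0.000541), Myc (0.0012), STAT5 (0.00286), S phase (0.013), glycolysis (0.0324), the unfolded-protein and amino acid response (0.0324), immediate early genes (0.0324) and STAT6 (0.0411). None held with an estimated correlation, where the lowest adjusted p was 0.065 (megakaryocyte and erythroid).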

How the results depend on the processing

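Runs without ILC2sn libraries 3 and 4, without libraries 1 and 2, and with length and GC offsets were chosen after seeing the result; the others were planned.

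Counts that moved by more than 1.5-fold follow by edgeR unless another tool is named; the cause was not tested. IL-33 against medium (24): DESeq2 86, no filter 46, only the 2 groups 62, without ILC2sn 3 and 4 167, without 1 and 2 121, offsets 57, and 6 (without IL-33 library 2) to 29 without 1 library. ILC2sn against medium (19): DESeq2 109, no filter 69, only the 2 groups 4, 29 and 5928 without the pairs, offsets 68, and 6 to 35 without 1 library. IL-33-ILC2sn against ILC2sn (1424): no filter 939, only the 2 groups 368, 5285 and 4228 without the pairs, and 703 to 1840 without 1 library. IL-33-ILC2sn against IL-33 (569): DESeq2 880, only the 2 groups 2084, 1789 and 1530 without the pairs, offsets 1102, and 242 to 365 without 1 library. IL-33-ILC2sn against medium (2430): only the 2 groups 4811, 5150 and 4849 without the pairs, and 1382 to 2134 without 1 library. Difference of the effects (5): DESeq2 90, stricter filter 9, 372 and 2330 without the pairs, offsets 35, and 1 to 8 without 1 library; all groups enter it, so a run with only the groups does not exist. Size factors of DESeq2 in edgeR moved the median log2 fold change by at most 0.0107, and the offsets by at most 0.0137.

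Lists that passed camera fell from 20, 19, 23, 17, 22 and 13 to 8, 4, 8, 8, 13 and 0 with an estimated correlation, and by fry to 6 for ILC2sn against medium and 1 for the difference. For ILC2sn against medium 9 passed without ILC2sn 3 and 4, and 12 with offsets; for the difference 8 passed without 1 and 2. Without 1 library the lists were 18 to 21, 10 to 19, 20 to 25, 17 to 19, 21 to 23 and 7 to 16.

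Directions reversed in 18 tests. Without ILC2sn 3 and 4, against medium: cytokines (camera adjusted p = 0.988), type I interferon (0.521), interferon-gamma (0.000664), Myc (0.413), ribosomal (7.52e-31) and oxidative phosphorylation (1.48e-17); IL-33-ILC2sn against ILC2sn: interferon-gamma (0.704) and, by edgeR, Rpl18a (log2 0.318); difference: ribosomal (9.28e-21). Without 1 and 2, IL-33-ILC2sn against ILC2sn: ribosomal (1.41e-13), oxidative phosphorylation (4.29e-07) and Mki67 (log2 0.456); difference: oxidative phosphorylation (3.61e-12), unfolded protein (0.761). Without 1 library: ribosomal proteins (list), IL-33 against medium (0.993 without medium 3, else down to 5.17e-05), ribosomal proteins (list), ILC2sn against medium (0.214 without ILC2sn 3, others 5.13e-08 to 0.727) and the difference (0.00486 without ILC2sn 3, others up to 0.902), and oxidative phosphorylation (list), IL-33-ILC2sn against ILC2sn (0.968 without ILC2sn 2, others down to 4.54e-08).

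The correlation of the 2 IL-33 effects (0.466) was 0.622 for genes of at least 5 CPM, 0.254 without ILC2sn 1 and 2, and 0.38 to 0.513 without 1 library.

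Replicate numbers did not pair libraries of different groups: 19 pairs of the same number had residual correlations of −0.267 to 0.288. With the number as a block the counts were 10, 7, 955, 367, 1978 and 0, against 24, 19, 1424, 569, 2430 and 5.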

Other observations

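The readings in this part and the count of shared calls were chosen after seeing the result; the list tests and the genes Kit, Ly6a, Flt3, Procr and Mki67 were fixed beforehand.

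Single stress genes rose together with the metabolic programme in cells given the supernatant of IL-33-treated ILC2s. Against medium, by edgeR with Benjamini-Hochberg adjustment over all genes, the stress response gene Atf3 rose by a log2 fold change of 2.95, the haem oxygenase gene Hmox1 by 2.50 and Klf2, a gene of cell quiescence, by 2.25. The quiescence list as a whole did not move (5 up and 5 down of 25, camera adjusted p = 0.797). Pmaip1, a gene of p53-driven death, stood at 9.24 ± 1.05 CPM in medium and 24.5 ± 1.7 CPM with IL-33-ILC2sn. Lipg and Scd1, both of lipid handling, rose with the sterol genes, which makes lipid supply a question for a direct measurement.

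The genes of the 2 proteins by which LSK cells are sorted moved apart against medium, with Ly6a up and Kit down. Of other surface genes of stem and progenitor cells, Procr rose and Flt3 fell. Whether the surface proteins follow was not measured here; staining of Sca1 and cKit after the culture would test it.

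IL-33 left over in the supernatant of the IL-33-treated ILC2s could act on the LSK cells directly: 23 of the 24 genes called with IL-33 alone were also called in the same direction in IL-33-ILC2sn against ILC2sn, which fits. IL-33 left over does not by itself account for the 569 genes that differed between IL-33-ILC2sn and IL-33 alone, unless its dose was higher. A supernatant with IL-33 blocked or removed would part the 2 sources.

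IL-2 and IL-7 of the ILC2 cultures may act on LSK cells through STAT5 in both supernatant groups. The STAT5 list in ILC2sn against medium had a camera adjusted p of 0.071 and cannot tell. Its mean log2 difference from medium was −0.007 and −0.002 in ILC2sn libraries 1 and 2, within the range of the medium libraries (−0.037 to 0.032). In libraries 3 and 4, which stood apart, it was 0.285 and 0.245. Medium with IL-2 and IL-7 was not among the groups.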
